A study of Sus scrofa with 12 samples.

How the data were processed

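Small RNA was sequenced in 12 libraries from pig liver (Sus scrofa) of 2 breeds, Bama and Hezuo. Each breed had 3 libraries at a normal temperature of 23 ± 2 °C and 3 under cold at -15 ± 2 °C, all from day 15. The labels use the same pig numbers, 1 to 3, at both temperatures and do not say whether a number names the same animal. The libraries were treated as 12 separate animals, which the sources used here do not state. Within a breed, libraries of the same number at both temperatures correlated in their deviations from the group mean at 0.00785 to 0.168, and 3 of 6 normal libraries were closest to the cold library of their number. A fit with the number as a block is among the alternatives. Its 3 levels are shared by both breeds, so it joins pigs of the same number across breeds. It is therefore no test of the same animal at both temperatures, and a pairing by breed and number was not run. Per the labels' protocols, total RNA was isolated with TRIzol, molecules of 18 to 30 nt were selected on a polyacrylamide gel, adapters were ligated to both ends, and the amplified library was recovered as a band near 140 bp. Sequencing instrument, batch, sex, age and litter are not given in the sources used here.

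The deposited table held 774 entries, each with a name, a mature sequence, its length and a class. Of these, 303 carried porcine names with the prefix ssc, 379 carried names from other species with the letters x, y or z in place of an arm number, and 92 were predicted miRNAs. Per the file headers, each library had a column of raw tag counts and a column of TPM, scaled to the total tags of the library. The counts were whole numbers and their sums over libraries equalled the table's total column. The deposited TPM values equalled the counts divided by 1 constant per library, with a count of 0 written as 0.01 TPM. The listed counts made up 84.3% to 88.2% of the library totals that these TPM values imply, so some tags of each library are outside the table. The aligner, the miRNA database, the prediction tool, the genome build and any earlier filter are not given in the sources used here. Of the file's lines, 2 had been emptied before use, and their contents are unknown.

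All tests used the deposited counts; the TPM columns served only to derive the library totals. The listed counts summed to 7184168 to 10384074 per library. The differences between pigs far exceeded counting error: the chi-squared statistic per degree of freedom between replicate libraries lay above 36.9 in every pair. Several entries are length forms or close relatives of the same sequence, and 47 entries had counts identical in every library with another entry (20 distinct profiles). How the authors divided tags among such entries is not given, so members of families that differ by 1 base are uncertain individually. PCR duplicates cannot be recognised, so the bounds given for a count of 0 cover counting error only.

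Differential abundance was tested with edgeR 4.0.16 under R 4.3.3: TMM scaling, the filterByExpr filter by group, robust dispersion estimates, quasi-likelihood F tests and Benjamini-Hochberg adjustment, with an adjusted p below 0.05 as a call. One model with a coefficient per group used all 12 libraries and 460 entries that passed the filter. The 6 contrasts were cold against normal in Hezuo, cold against normal in Bama, the difference between these responses (the interaction), cold against normal averaged over both breeds, and Hezuo against Bama at normal temperature and under cold. CPM values are counts scaled to the TMM-adjusted library size; standard errors of log2 differences were derived from the F statistics. The biological coefficient of variation was 25%.

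Before the data were examined, 23 lists of miRNAs were fixed: liver-enriched miRNAs, lipid and cholesterol metabolism, glucose and insulin, brown fat and thermogenesis, hypoxia, oxidative stress and p53, inflammation, fibrosis, the let-7, miR-29 and miR-30 families, the clusters miR-17 and miR-92 with paralogs, miR-183 with miR-96 and miR-182, the imprinted DLK1-DIO3 locus and X-linked miR-424 with miR-503, and markers of erythroid, myeloid, lymphoid, endothelial, stellate with fibroblast and smooth muscle, biliary and other epithelial, muscle, and nervous and endocrine cells. Several miRNAs stand in more than 1 list. Each list was tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2) and adjusted over the 23 lists of a contrast. Camera with the correlation estimated from the data, and fry, were run beside it. None of the camera calls in any contrast held with an estimated correlation.

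The miRNAs named in the text follow a rule fixed at the same time. For the temperature contrasts within each breed and the interaction, these are up to 8 called miRNAs per direction with the largest change, non-overlapping groups (not asked of the interaction), at most 2 predicted miRNAs and a mean of at least 10 CPM in a group. For the other contrasts the number is 5. Where fewer than 3 passed in a direction, the 5 with the smallest p in that direction are given as values that did not pass. Up to 4 called members per list, the 5 most abundant miRNAs, and miR-122 and miR-210 complete the rule; miR-122 and miR-210 were taken from the entries with porcine names. MiRNAs outside the rule were chosen after their values were seen: miR-140-3p over both breeds, miR-204-y and miR-194a-5p under cold, miR-9843-3p, m0017-3p, and the list members given only as passing adjusted over the list alone.

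The shares of counts taken by the most abundant miRNAs were compared between temperatures by exact two-sided permutation within breed (400 arrangements, smallest possible p 0.005), adjusted over 5 measures. Each model-based count of calls was also computed for other splits of the same libraries, 100 of them drawn with a fixed seed where more existed.

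Alternatives fixed in advance were DESeq2 size factors, library totals and upper quartile scaling, no filter and a mean of at least 10 counts, DESeq2 1.42.0, limma-voom, a fit of only the compared groups, replicate number as a block, omission of predicted miRNAs and of the most abundant miRNA, a threshold of unadjusted p below 0.05 with a 2-fold change, and omission of each library in turn. Chosen after seeing the data were the collapse of identical entries, the summing of entries that share their first 16 nt, and the omission of 21 entries of at most 20 nt that end in CCA as transfer RNA does.

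The scripts were tested on simulated counts with known changes, drawn from the means, library sizes and dispersions of the real data. For cold in Hezuo (448 entries tested), 20.5% of simulated 1.5-fold, 55% of 2-fold and 78.0% of 4-fold changes were called; for cold in Bama (461 entries) 22.9%, 41.5% and 84.8%; for the interaction (445 entries) 8.11%, 30.3% and 60%; for cold over both breeds (450 entries) 50%, 76.2% and 100%. The breed contrasts gave 17.1%, 53.5% and 86.4% at normal temperature (469 entries) and 33.3%, 40% and 86.1% under cold (446 entries). False calls made up 0% to 4.76% of all calls. Many entries were changed at once: for cold in Hezuo 39 by 1.5-fold, 40 by 2-fold and 41 by 4-fold, with 63 calls. Where fewer miRNAs change, the adjustment is stricter, so these shares can be too high for the real contrasts. MiRNA genes were looked up by name in the RefSeq annotation of Sscrofa11.1, where 256 of the 303 porcine names matched. Their host genes and neighbours were taken from the positions in that annotation. No coordinates of the deposited entries were used, because their genome build is unknown.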

Results

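Pig livers were profiled in 12 small RNA libraries, all labelled day 15. The aim was to find miRNAs that respond to cold and that distinguish the Hezuo breed, studied for its cold resistance, from the Bama breed. Each of the 4 groups (Bama normal, Bama cold, Hezuo normal, Hezuo cold) had 3 libraries, and the normal-temperature group of each breed was its control. The listed miRNA counts per library averaged 7476605 ± 143086 (SD, n = 3) in Bama normal, 8335010 ± 1500770 in Bama cold, 9293570 ± 1022240 in Hezuo normal and 7797451 ± 452881 in Hezuo cold. Between 655 and 694 of the 774 entries had counts in a library. The first principal component held 30.2% of the variance and separated the breeds.

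Liver miRNA was dominated by miR-122-5p, the hepatocyte miRNA, and miR-148a-3p, and cold shifted the balance between them. The share of miR-122-5p was 53.5% ± 3.26 (SD, n = 3) in Bama normal and 48.6% ± 1.66 in Bama cold, and 53.6% ± 3.04 in Hezuo normal and 46.1% ± 2.94 in Hezuo cold. Averaged over breeds it fell by 6.23 percentage points (exact permutation within breed p = 0.01, adjusted 0.025). The share of miR-148a-3p rose from 22.0% ± 2.71 to 27.6% ± 1.32 in Bama and from 22.8% ± 1.55 to 28.7% ± 1.45 in Hezuo, every cold liver above every normal liver of its breed (exact permutation p = 0.005, the smallest these arrangements can give, adjusted 0.025). In counts that leave out miR-148a-3p, the share of miR-122-5p was 69.0% at normal temperature and 65.9% under cold (exact permutation p = 0.035). With 1 library left out, that p stayed below 0.05 without Bama normal 2 (0.025), Bama cold 3 (0.035) or Hezuo cold 2 (0.025), and was 0.055 to 0.1 without any 1 of the other 9. The 10 most abundant miRNAs together took 90.4% at normal temperature and 90.2% under cold (exact permutation p = 0.54, adjusted 0.675). In the TMM-scaled fit over both breeds, miR-122-5p at -0.26 (SE 0.09, adjusted p = 0.196) and miR-148a-3p at 0.26 (SE 0.08, adjusted p = 0.118) did not pass. Within 1 breed the smallest p that an exact test can give is 0.1. The listed part of the libraries averaged 87.6% of all tags under cold and 86.4% at normal temperature (exact permutation p = 0.02, adjusted 0.0333), a difference of 1.87 percentage points in Bama and 0.50 in Hezuo. The average difference of 1.19 was 0.777 without Bama normal 2, and p was 0.075, 0.065 and 0.06 without Bama cold 1, 2 and 3.

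**Figure D1:**
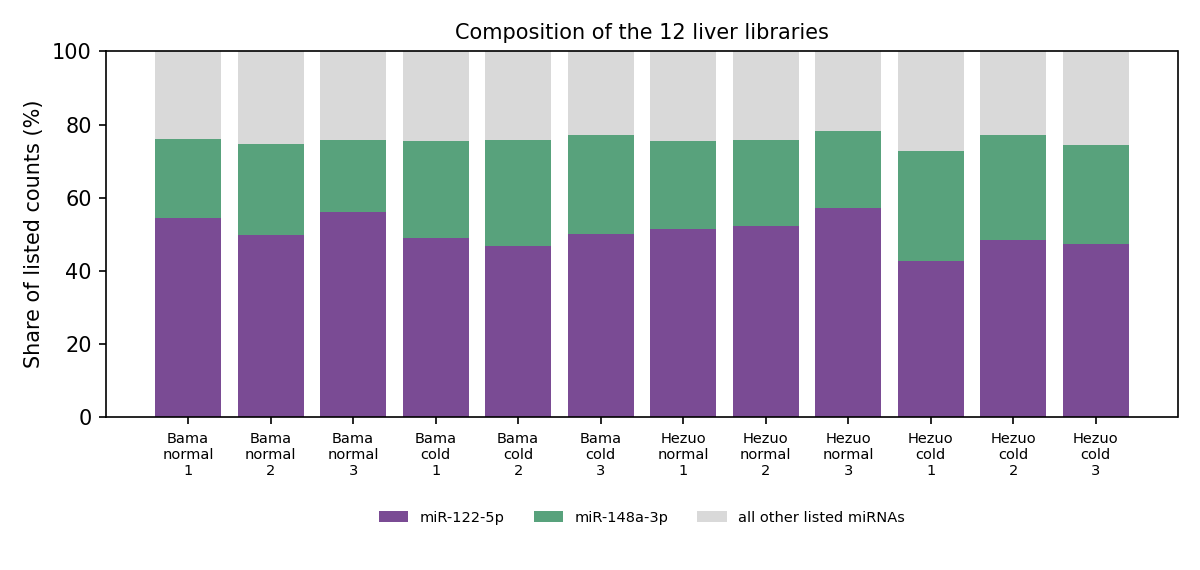
Stacked bars give the share of listed counts (%, vertical axis from 0) taken by miR-122-5p, miR-148a-3p and all other listed miRNAs in each of the 12 liver libraries. The miR-122-5p share averaged 53.6% at normal temperature and 47.3% under cold, and the miR-148a-3p share 22.4% and 28.2%.

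What cold did to liver miRNAs in both breeds was asked with 6 cold against 6 normal livers. MiR-29b, a repressor of collagen mRNAs, rose by 0.84 log2 units (SE 0.14, adjusted p = 0.0035). It went from 12.6 ± 0.341 to 28.1 ± 3.74 CPM (SD, n = 3) in Bama and from 10.8 ± 1.79 to 15.6 ± 2.06 CPM in Hezuo. MiR-7-5p, best known from endocrine and nervous cells, rose by 0.58 (SE 0.11, adjusted p = 0.00857). Both strands of miR-140, whose gene lies in WWP2 in the pig annotation (Sscrofa11.1), rose, miR-140-5p by 0.40 (SE 0.09, adjusted p = 0.04) and miR-140-3p by 0.45 (SE 0.08, adjusted p = 0.00857). MiR-378, a regulator of fat and energy metabolism with 1 of its genes in PPARGC1B, rose by 0.61 (SE 0.12, adjusted p = 0.0174), with its longer form miR-378-y at 0.70 (SE 0.16, adjusted p = 0.04). MiR-192-z, a 24-nt form of the liver miRNA miR-192, fell by 0.72 (SE 0.11, adjusted p = 0.0035), and miR-181-y, the 3p strand of miR-181, fell by 0.84 (SE 0.13, adjusted p = 0.0035).

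In total 10 miRNAs passed over all miRNAs tested, 6 higher and 4 lower; let-7c (-0.31, SE 0.07, adjusted p = 0.04) and miR-455-3p (-0.98, SE 0.24, adjusted p = 0.0471) complete the list. MiR-140-3p was chosen after its values were seen. All 10 had the same sign in both breeds, and in 8 of them every cold liver lay beyond every normal liver in each breed. Chance gives such a double separation in 0.5% of miRNAs, and 13 of the 460 tested (2.83%) had it. The 10 were called on the average of both breeds in these same libraries. Their signs and separation are therefore no separate evidence from each breed, and in Hezuo alone 0 of the 460 passed by edgeR. MiR-192-x (23 nt) and miR-192 (21 nt), other forms of miR-192, were at -0.34 (SE 0.10, adjusted p = 0.0999) and -0.07 (SE 0.10, adjusted p = 0.694), values that did not pass. With forms that share their first 16 nt summed, miR-192 was at -0.30 (adjusted p = 0.126). MiR-204 at -0.70 and miR-184 at -1.14 (both adjusted p = 0.0543) did not pass, nor did miR-143-3p at 0.05 (adjusted p = 0.844), miR-122-3p at -0.16 (adjusted p = 0.573) or the hypoxia miRNA miR-210 at -0.35 (adjusted p = 0.579), whose group means lay between 0.657 and 1.51 CPM. Let-7c differs from let-7a by 1 base, so its counts could be divided with its relatives.

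Among the lists, lipid and cholesterol metabolism rose (median 0.21, 20 of 25 members positive, camera adjusted p = 0.0147), but with an estimated correlation its adjusted p was 0.203. Glucose and insulin rose (median 0.21, 21 of 29 positive, adjusted p = 0.0147; adjusted p = 0.141 with an estimated correlation). The miR-29 family rose (median 0.42, 4 of 5 positive, adjusted p = 0.016; adjusted p = 0.541 with an estimated correlation). Of the glucose and insulin list, 3 members passed over all miRNAs and 4 adjusted over the list alone: miR-29a-3p, miR-29b, miR-378 and miR-378-y, all higher. No lipid list member passed either way. In brown fat and thermogenesis 2 rose and 1 fell over all miRNAs, and 2 rose and 2 fell adjusted over the list alone (miR-378 and miR-378-y higher, miR-455-5p and miR-455-3p lower), with a list median of 0.01 (adjusted p = 0.534). In the liver-enriched list (median -0.09, adjusted p = 0.341) 1 member fell over all miRNAs, and adjusted over the list alone miR-192-z and miR-192-x fell and miR-148a-3p rose.

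The other lists did not pass over both breeds. The imprinted DLK1-DIO3 cluster had 0 of 13 members positive by edgeR (median -0.61, adjusted p = 0.261), and the X-linked cluster of miR-424 and miR-503 had 0 of 10 (median -0.06, adjusted p = 0.357). The cluster of miR-17 and miR-92 with its paralogs had a median of -0.18, the cluster of miR-183, miR-96 and miR-182 of 0.31 and the miR-30 family of 0.08, each with an adjusted p of 0.261. In the let-7 family (median -0.13, adjusted p = 0.534) let-7c fell in both counts, over all miRNAs and adjusted over the list alone. The fibrosis list (median -0.11, adjusted p = 0.868) held miR-29b over all miRNAs and miR-29a-3p and miR-29b adjusted over the list alone, both higher. The medians were -0.06 for hypoxia (adjusted p = 0.534), -0.09 for oxidative stress and p53 (adjusted p = 0.365) and -0.11 for inflammation (adjusted p = 0.868). Among markers of other cell types, the medians were 0.15 for erythroid (adjusted p = 0.368), 0.13 for myeloid (0.365), -0.09 for lymphoid (0.717) and -0.13 for endothelial cells (0.534). They were -0.05 for stellate, fibroblast and smooth muscle cells (0.717), -0.12 for biliary and other epithelium (0.717), 0.28 for skeletal and heart muscle (0.341) and 0.24 for nervous and endocrine cells (0.261). With library totals the medians of hypoxia, the X-linked cluster and the stellate list were 0.02, 0.02 and 0.03, the opposite sign. Adjusted over the list alone, miR-7-5p and the endothelial miR-126-y were higher and the lymphoid miR-181a was lower.

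DESeq2 called 26 miRNAs, the fit without a filter 6 and sums over shared first 16 nt 5. Those sums ended the calls of miR-192-z (-0.30, adjusted p = 0.126), let-7c (-0.18, 0.212), miR-140-5p (0.106) and miR-455-3p (0.0762). With the pig number as a block, miR-140-5p, miR-455-3p (each adjusted p = 0.0711) and let-7c (0.0597) did not pass. Of 13 alternatives other than leaving out 1 library, let-7c and miR-455-3p passed in 2 (DESeq2 and the fit without miR-122-5p), being lost under each other scaling, both other filters and limma-voom among others. MiR-140-5p passed in 7, being lost also with DESeq2 size factors, without a filter, without miR-122-5p and with identical entries collapsed, and miR-378-y was lost only without a filter. The up and down calls were 6 and 4 with TMM, 5 and 2 with DESeq2 size factors, 8 and 2 with library totals, and 6 and 2 with upper quartile scaling. MiR-29b, miR-7-5p, miR-140-3p, miR-181-y and miR-192-z passed whichever library was left out. MiR-378 was lost without Hezuo cold replicate 2 (adjusted p = 0.0647), miR-378-y without any 1 of 9 libraries (all but Bama normal 2, Hezuo normal 2 and Hezuo cold 3; adjusted p up to 0.0953). MiR-140-5p, let-7c and miR-455-3p were lost without any 1 of 11 (all but Bama normal 3, Bama normal 2 and Bama normal 1 respectively; adjusted p up to 0.127, 0.162 and 0.145). The count was 6 without Bama cold 1, Bama cold 3 or Hezuo normal 1 and 5 without Hezuo cold 2. Without Bama cold 2 or Hezuo cold 3 none of these lists passed (adjusted p of 0.121 and 0.0803 for lipid and cholesterol metabolism, 0.0721 and 0.0803 for glucose and insulin, 0.0565 and 0.0963 for the miR-29 family), while without Bama cold 2 the DLK1-DIO3 cluster passed as lower (median -0.86, adjusted p = 0.00956; adjusted p = 0.819 with an estimated correlation). The lipid list was also lost without Bama normal 2 (0.0516) or Hezuo normal 3 (0.0521), and the glucose list without Bama normal 1 (0.0555) or Hezuo normal 2 (0.0503).

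**Figure D2:**
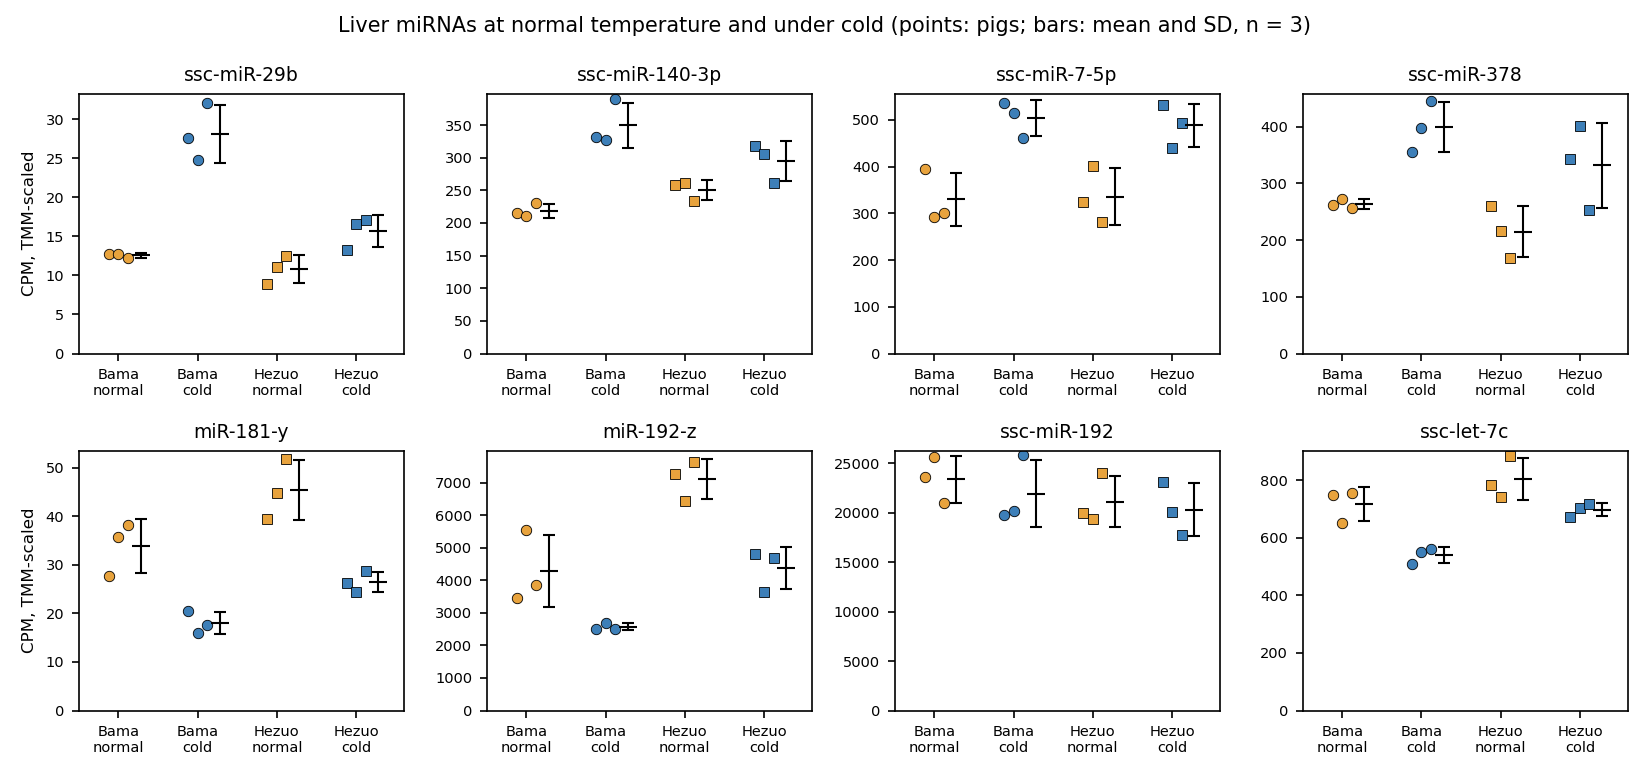
Points give TMM-scaled CPM (vertical axes from 0) of 8 miRNAs in each liver, by group, with horizontal bars for the mean and error bars for the SD (n = 3). MiR-29b averaged 12.6 CPM in Bama normal and 28.1 CPM in Bama cold livers, and 10.8 and 15.6 CPM in the Hezuo groups, while miR-192 (21 nt) overlapped between temperatures.

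In Bama pigs alone, 5 miRNAs changed under cold. MiR-29b rose 2.24-fold (1.16 log2 units, SE 0.19, adjusted p = 0.0106) and miR-29a-3p rose from 467.5 ± 15.1 to 676.1 ± 19.9 CPM (SD, n = 3, 0.53 log2 units, SE 0.12, adjusted p = 0.0409). In the pig annotation MIR29A lies beside MIR29B-1 and MIR29C beside MIR29B-2, so the counts do not tell which miR-29b gene responded. MiR-140-3p rose from 218.5 ± 10.9 to 349.4 ± 34.6 CPM (0.68, SE 0.12, adjusted p = 0.0106). MiR-181-y fell from 33.9 ± 5.53 to 18.0 ± 2.34 CPM (-0.91, SE 0.18, adjusted p = 0.0326) and miR-192-z from 4285 ± 1118 to 2572 ± 107 CPM (-0.74, SE 0.16, adjusted p = 0.0409). In each of the 5, all 3 cold livers lay beyond all 3 normal livers, and the sign was the same in Hezuo. Of the 460 tested, 16.7% had non-overlapping groups in Bama, where chance gives 10%, and 65.7% had the same sign in both breeds. The tests of the difference between the breeds gave -0.63 for miR-29b, -0.46 for miR-29a-3p and -0.44 for miR-140-3p (each adjusted p = 0.766), and 0.13 for miR-181-y and 0.04 for miR-192-z (each adjusted p = 0.998).

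Among the declines that did not pass, those with the smallest p were miR-204 at -1.06 (SE 0.25, adjusted p = 0.0552), let-7c at -0.41 (SE 0.10, adjusted p = 0.0552) and miR-455-5p at -0.63 (SE 0.16, adjusted p = 0.0686). Nor did the abundant miR-148a-3p (0.35, adjusted p = 0.143), miR-122-5p (-0.11, adjusted p = 0.743), miR-192-x (-0.31, adjusted p = 0.335), miR-192 (-0.09, adjusted p = 0.836) and miR-143-3p (-0.02, adjusted p = 0.973) pass, nor miR-122-3p (-0.14) and miR-210 (0.39). As a list, the miR-29 family rose (5 of 5 positive, median 0.53, camera adjusted p = 0.0209; adjusted p = 0.341 with an estimated correlation), with 2 members passing over all miRNAs and 2 adjusted over the list alone. The miR-30 family rose (12 of 13 positive, median 0.25, adjusted p = 0.0301; adjusted p = 0.543 with an estimated correlation), with 0 members passing by edgeR in either way. Glucose and insulin rose (21 of 29 positive, median 0.27, adjusted p = 0.0301; adjusted p = 0.25 with an estimated correlation), with 2 members passing over all miRNAs and 4 adjusted over the list alone, miR-378 and miR-378-y being added. Lipid and cholesterol metabolism rose (19 of 25 positive, median 0.28, adjusted p = 0.0301; adjusted p = 0.341 with an estimated correlation), with 0 members passing by edgeR. The differences between the breeds in these lists had a median of -0.46 for the miR-29 family (adjusted p = 0.195), -0.06 for glucose and insulin (0.697) and -0.13 for the lipid list (0.785), and with library totals the last pair turned to 0.14 and 0.02. The fibrosis list, which also holds the miR-29 genes, had a median of -0.12 (7 of 23 positive, adjusted p = 0.693). Adjusted over the list alone miR-29a-3p and miR-29b rose and miR-199b-5p fell. No cell type list passed by camera. Medians were 0.53 for nervous and endocrine (adjusted p = 0.384), 0.41 for erythroid (0.4), 0.14 for myeloid, 0.13 for lymphoid and 0.10 for muscle markers. They were -0.11 for endothelial, -0.11 for stellate, fibroblast and smooth muscle, and -0.16 for biliary and other epithelial markers.

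Counts of calls ranged from 0 in a fit of the Bama libraries alone and 1 with library totals (1 up) to 21 with DESeq2, with 67 miRNAs at an unadjusted p below 0.05. Upper quartile scaling gave 4 up and 0 down against 3 up and 2 down with TMM, and sums over shared first 16 nt or a mean of 10 counts gave 3. In those sums miR-192 was at -0.31 (adjusted p = 0.32) and miR-29a-3p at 0.48 (adjusted p = 0.0695). With the pig number, shared by both breeds, as a block 2 of the 5 passed, miR-29b (adjusted p = 0.0337) and miR-140-3p (0.0448). MiR-29a-3p, miR-181-y (each 0.0540) and miR-192-z (0.107) did not. That block does not pair animals within Bama, so a pairing by animal was not tested. Of 14 alternatives other than leaving out 1 library, miR-29b passed in 13, miR-140-3p in 12, miR-181-y in 10, miR-192-z in 7 and miR-29a-3p in 6. Library totals ended all but miR-29b, and upper quartile scaling ended miR-181-y and miR-192-z. Library totals also ended the calls of the lipid list (adjusted p = 0.0663), glucose and insulin (0.0503) and the miR-30 family (0.0794). By fry the lipid list (0.057) and the miR-30 family (0.126) did not pass. Fry also called the cluster of miR-183, miR-96 and miR-182 (3 of 3 positive, median 0.52, adjusted p = 0.0477), for which camera gave an adjusted p of 0.139. The count was 0 without Bama normal replicate 2 or Bama cold replicate 3, 2 without Bama cold replicate 1 and 3 without Bama normal replicate 3. MiR-29b and miR-140-3p passed without any of the other 4 libraries, miR-181-y and miR-192-z only without Bama normal replicate 1, and miR-29a-3p in none of the 6 (adjusted p 0.0582 to 0.181). Without Bama normal 1 the glucose list and the miR-30 family were lost (0.0971 and 0.231), and without Bama cold 2 these and the lipid list (0.236, 0.234 and 0.336), while the DLK1-DIO3 cluster passed as lower without Bama cold 2 (median -0.99, adjusted p = 0.00383; adjusted p = 0.811 with an estimated correlation). The lipid list was also lost without Bama normal 2 (adjusted p = 0.154), Bama normal 3 (0.116) and Bama cold 1 (0.0748) and the miR-30 family without Bama cold 3 (0.0955).

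In Hezuo pigs alone, the breed of interest, the same miRNAs pointed the same way but 0 of 460 passed by edgeR. There were 43 at an unadjusted p below 0.05 (19 higher, 24 lower), and 0 were called by DESeq2 and by limma-voom. The values that did not pass were led by miR-192-z, at 7113 ± 617 CPM (SD, n = 3) in normal and 4376 ± 650 CPM in cold livers (-0.70, SE 0.16, adjusted p = 0.176), and miR-181-y, at 45.4 ± 6.16 and 26.5 ± 2.14 CPM (-0.78, SE 0.18, adjusted p = 0.176). MiR-7-5p was at 335.8 ± 60.8 and 488.3 ± 46.6 CPM (0.54, SE 0.15, adjusted p = 0.355), miR-378 at 0.63 (SE 0.18), miR-9, a neuronal miRNA, at 0.95 (SE 0.30), miR-29b at 0.53 (SE 0.19) and miR-1, a muscle miRNA, at 0.71 (SE 0.26), with adjusted p of 0.355 to 0.37. Downward values were miR-181a at -0.38 (SE 0.12), miR-10014-x at -1.001 (SE 0.31) and miR-122-5p at -0.40 (SE 0.13), each with an adjusted p of 0.355. Of all these, only miR-378 had overlapping groups. Among the 460 tested, 15.4% had non-overlapping groups in Hezuo, and chance gives 10%.

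MiR-148a-3p (0.16), miR-192-x (-0.36), miR-192 (-0.06), miR-143-3p (0.12), miR-122-3p (-0.18) and miR-210 (-1.10, at 1.42 and 0.657 CPM) had adjusted p of 0.427 to 0.949. No list passed by camera (0 by fry; 4 at an unadjusted p below 0.05). Glucose and insulin had 22 of 29 members positive (median 0.13, adjusted p = 0.143) and lipid and cholesterol metabolism 17 of 25 (median 0.14, adjusted p = 0.143). Adjusted over the list alone, miR-192-z was lower in the liver-enriched and the oxidative stress lists, miR-1 higher among muscle markers, and miR-7-5p and miR-9 higher among nervous and endocrine markers. The imprinted DLK1-DIO3 cluster had 13 of 13 members negative (median -0.75, adjusted p = 0.415). It passed without Hezuo normal replicate 3 (median -0.99, adjusted p = 0.000108), the 1 library that moved the list count here, although its adjusted p was 0.832 with an estimated correlation.

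Whether the breeds differ in their response was tested by the interaction. MiR-29a-3p was 676.1 ± 19.9 CPM (SD, n = 3) in Bama cold against 517.3 ± 38.3 CPM in Hezuo cold livers, from similar normal levels, and its interaction of -0.46 (SE 0.16) did not pass. Likewise miR-140-3p (-0.44, SE 0.16), miR-101 (-0.45, SE 0.16), miR-30a-5p (-0.33, SE 0.13) and miR-508-y (-1.58, SE 0.50) lay lower in the Hezuo response, and miR-574-5p (0.95, SE 0.29), miR-9 (0.99, SE 0.41), miR-6715-z (1.504, SE 0.61), the predicted miRNA m0002-3p (1.06, SE 0.45) and miR-1 (0.85, SE 0.36) higher. All had an adjusted p of 0.766. In all, 0 of 460 miRNAs passed by edgeR (25 at an unadjusted p below 0.05), and DESeq2 and limma-voom also called 0. The most abundant miRNAs had values of -0.28 (miR-122-5p), -0.19 (miR-148a-3p), -0.05 (miR-192-x), 0.03 (miR-192), 0.14 (miR-143-3p) and -0.04 (miR-122-3p), and miR-210 was at -1.49 (adjusted p = 0.766).

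The miR-30 family, abundant miRNAs shared by many tissues, was lower in the Hezuo response in 13 of 13 members (median -0.29, camera adjusted p = 0.0464; adjusted p = 0.611 with an estimated correlation), with 0 members passing by edgeR over all miRNAs or adjusted over the list alone. In Bama the members had a median of 0.25, and in Hezuo -0.04 (adjusted p = 0.792). With library totals, which moved the median interaction of all miRNAs by 0.19, the Hezuo median was 0.14 and 8 of 13 interaction values were negative. The call was lost with library totals (adjusted p = 0.341), with the pig number as a block (0.0893), with fry (0.584) and without any 1 of 9 libraries, with adjusted p from 0.0772 to 0.346; it held without Bama cold 1, Hezuo normal 2 or Hezuo cold 1.

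**Figure D3:**
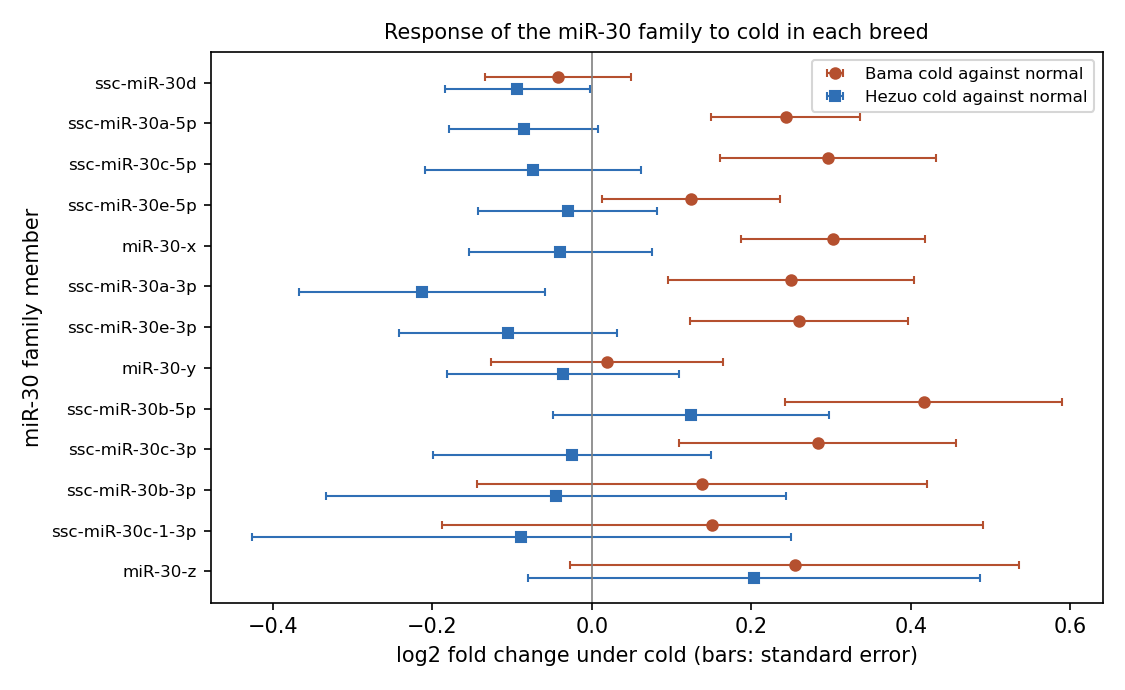
Log2 fold change under cold (horizontal axis) of the 13 measured miR-30 family members in Bama (circles) and Hezuo (squares) livers, with bars for the standard error. MiR-30a-5p lay at 0.24 in Bama and -0.09 in Hezuo, and with library totals in place of TMM the Hezuo values moved above 0 in 12 of 13 members.

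Across miRNAs, the log2 responses of the breeds correlated with Pearson r = 0.315 and Spearman rho = 0.39 (460 miRNAs, which are not independent replicates), and 302 (65.7%) had the same sign. The groups compared share no libraries. Among 236 miRNAs at 10 or more CPM, r was 0.469; without a filter it was 0.0532. Leaving out 1 library gave r between 0.169 and 0.276, and the values without Bama normal 1 (0.187), Bama normal 3 (0.195), Hezuo normal 2 (0.209) and Hezuo cold 3 (0.169) were lower by more than 1.5 times.

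Among miRNAs with a mean of 10 or more CPM in a group at normal temperature, Hezuo livers were set apart from Bama livers above all by miR-204 and miR-184. MiR-204, whose gene lies in TRPM3, was 417 ± 69.7 CPM (SD, n = 3) in Hezuo and 90.4 ± 18.2 CPM in Bama, 4.61-fold higher (2.21 log2 units, SE 0.25, adjusted p = 0.000417). The opposite strand miR-204-y was 2.83 higher (SE 0.45, adjusted p = 0.00316) and the longer form miR-204-x 2.55 higher (SE 0.42, adjusted p = 0.00376). MiR-184, known from lens and neural tissue, was 4.52 ± 2.53 CPM in Hezuo and 35.7 ± 8.995 CPM in Bama (-2.99, SE 0.40, adjusted p = 0.000954). MiR-508-y (1.84, SE 0.36, adjusted p = 0.0135) and miR-182 (1.23, SE 0.31, adjusted p = 0.0446) were higher in Hezuo, and miR-455-5p (-0.73, SE 0.16, adjusted p = 0.023), miR-151-3p (-0.50, SE 0.13, adjusted p = 0.0455) and the X-linked miR-450c-5p (-0.48, SE 0.12, adjusted p = 0.0455) lower. For every miRNA named in this paragraph all 3 Hezuo livers lay beyond all 3 Bama livers, which the naming rule asked for. Of the 460 tested, 22.2% had non-overlapping groups, and chance gives 10%.

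Of 17 miRNAs that passed, 12 were higher and 5 lower in Hezuo. Liver-enriched miRNAs were higher as a list (19 of 25 positive, median 0.33, camera adjusted p = 0.00792; adjusted p = 0.662 with an estimated correlation), with 2 members passing over all miRNAs, miR-192-z (0.73, SE 0.16, adjusted p = 0.0218) and miR-101-y (0.58, SE 0.12, adjusted p = 0.0135), and 4 adjusted over the list alone, miR-101 and miR-194b-5p being added. The X-linked cluster of miR-424 and miR-503 was lower in 10 of 10 members (median -0.42, adjusted p = 0.00234; adjusted p = 0.496 with an estimated correlation), with 1 passing over all miRNAs and 4 adjusted over the list alone: miR-450c-5p, miR-450a, miR-542-3p and miR-450b-5p. With upper quartile scaling 8 of 10 were lower. Fry called only the cluster of miR-183, miR-96 and miR-182 (3 of 3 positive, median 0.82, adjusted p = 0.0482), for which camera gave an adjusted p of 0.152 (0.496 with an estimated correlation); its adjusted p was 0.114 for the liver-enriched list and 0.0960 for the X-linked cluster. Erythroid markers, which share miR-182 and miR-96 with that cluster, were positive in 8 of 8 (median 0.91, adjusted p = 0.14). Markers of stellate, fibroblast and smooth muscle cells were positive in 6 of 18 (median -0.17, adjusted p = 0.14), and the medians were -0.62 for biliary and other epithelium (adjusted p = 0.297), -0.28 for myeloid (0.287) and 0.20 for endothelial cells (0.348). In the miR-30 family 1 member passed over all miRNAs and adjusted over the list alone, miR-30-x (0.47, SE 0.12, adjusted p = 0.0437), and the family median was 0.09 (adjusted p = 0.512; -0.05 with library totals).

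MiR-192-z, miR-101-y, miR-204-x and miR-30-x are longer forms of other entries. Over 22 miRNAs other than miR-192, with miR-101, miR-204 and miR-30a-5p among them, the median log2 ratio of the longer to the shorter form was higher in Hezuo than in Bama by 0.27 over both temperatures, in a test chosen after the result was seen (exact permutation within temperature p = 0.005, the smallest possible). The liver-enriched list, which holds miR-192-z and miR-101-y, was not tested with forms summed, so how far its call rests on longer forms is unknown. Among abundant miRNAs, miR-122-5p (0.16), miR-148a-3p (0.20), miR-192-x (0.36), miR-192 (-0.15), miR-143-3p (-0.41) and miR-122-3p (-0.07) had adjusted p of 0.174 to 0.887, and miR-210 was at 0.33 (adjusted p = 0.716).

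The count was 37 with DESeq2, 10 in a fit of the normal-temperature libraries alone, 32 without miR-122-5p (12 up, 20 down) and 27 without short entries ending in CCA, and the 12 up and 5 down of TMM became 7 and 15 with library totals and 25 and 2 with upper quartile scaling. Library totals moved the median of all miRNAs by -0.14 and upper quartile scaling by 0.14. With forms that share their first 16 nt summed, miR-192 was at 0.27 (adjusted p = 0.303) and miR-30-x with its relatives at 0.29 (0.134), and miR-455-5p (0.0543), miR-151-3p (0.0531) and miR-450c-5p (0.0808) did not pass either. With the pig number as a block, miR-182, miR-151-3p, miR-450c-5p, miR-30-x (each adjusted p = 0.0680) and miR-192-z (0.0535) did not pass. Of 14 alternatives other than leaving out 1 library, miR-455-5p and miR-101-y passed in 12, miR-182 in 11, miR-192-z in 10, miR-151-3p in 9, miR-450c-5p in 7 and miR-30-x in 6. Library totals ended miR-182, miR-101-y, miR-192-z and miR-30-x, upper quartile scaling ended miR-455-5p, miR-151-3p and miR-450c-5p, and DESeq2 size factors ended miR-30-x. Without Bama normal 3 or Hezuo normal 3 the count was 4, without Bama normal 1 it was 8 and without Hezuo normal 1 it was 11. MiR-204 in its 3 forms and miR-184 passed in all 6 fits. MiR-508-y was lost without Bama normal 3 or Hezuo normal 3, miR-101-y also without Bama normal 1, miR-182 and miR-192-z also without Hezuo normal 1. MiR-455-5p was lost without Bama normal 3 or any Hezuo library, miR-151-3p without any library but Bama normal 2, miR-30-x without any but Hezuo normal 2, and miR-450c-5p in all 6 (highest adjusted p 0.0962, 0.118, 0.163, 0.13, 0.102, 0.165, 0.206 and 0.201 in this order). The liver-enriched list was lost without Bama normal 1 (adjusted p = 0.162) or Hezuo normal 3 (0.104).

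**Figure D4:**
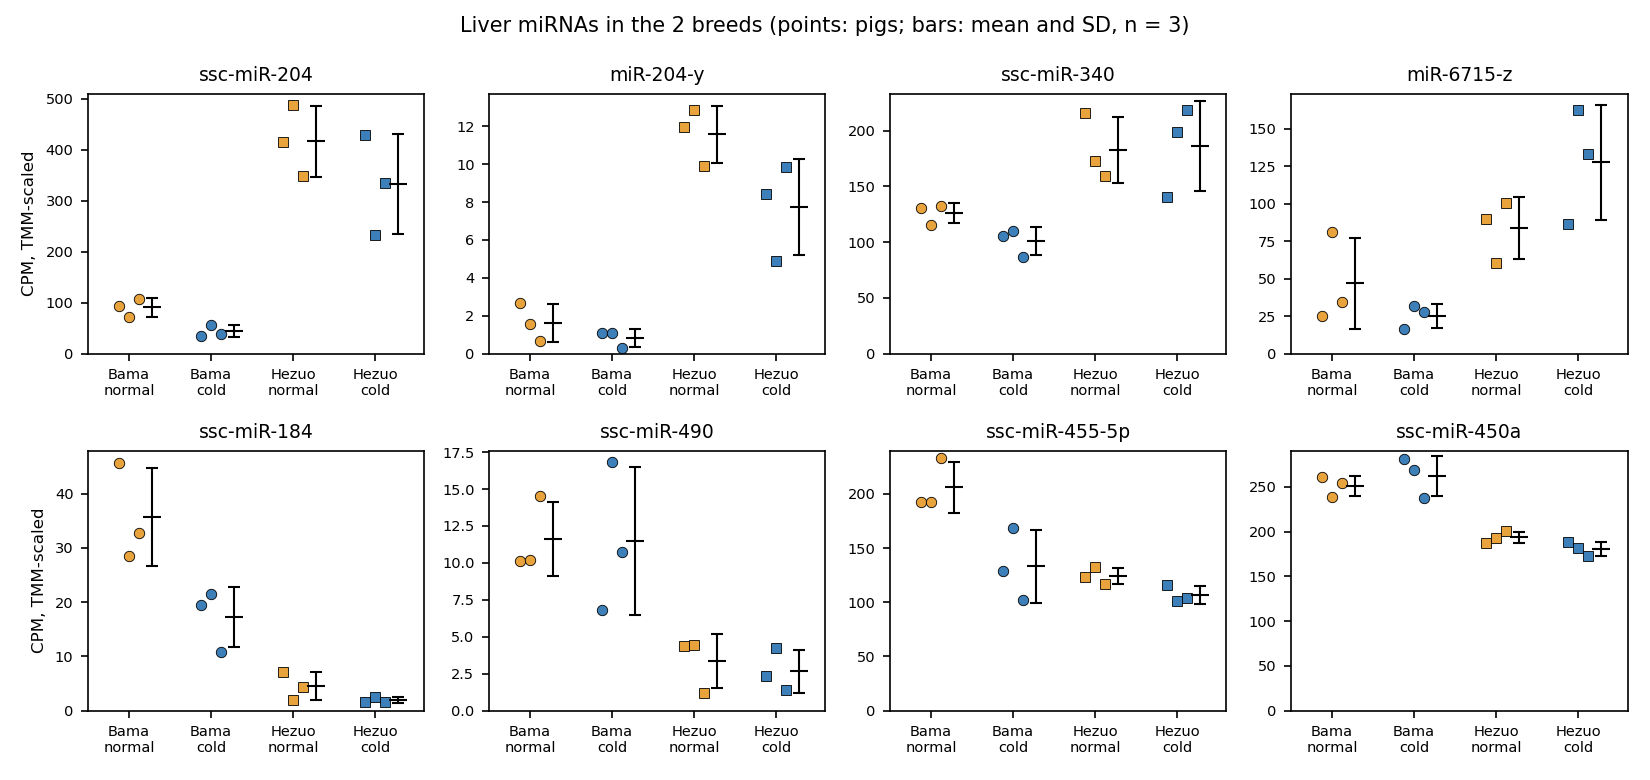
Points give TMM-scaled CPM (vertical axes from 0) of 8 miRNAs in each liver, by group, with horizontal bars for the mean and error bars for the SD (n = 3). MiR-204 averaged 417 CPM in Hezuo normal and 332.2 CPM in Hezuo cold livers against 90.4 and 43.3 CPM in Bama, and miR-184 lay lower in each Hezuo group.

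Under cold the same miRNAs, miR-204 and miR-184, set the breeds apart. MiR-204 was 332.2 ± 98.0 CPM (SD, n = 3) in Hezuo and 43.3 ± 11.8 CPM in Bama, 7.68-fold higher (2.94 log2 units, SE 0.26, adjusted p = 2.3e-05), with miR-204-x 3.97 higher (SE 0.47, adjusted p = 0.000257) and miR-204-y, chosen after its values were seen, 3.22 higher (SE 0.49, adjusted p = 0.00147). MiR-184 was 1.90 ± 0.594 CPM in Hezuo and 17.3 ± 5.62 CPM in Bama (-3.18, SE 0.43, adjusted p = 0.000714). MiR-340 (0.88, SE 0.17, adjusted p = 0.011), miR-6715-z (2.34, SE 0.45, adjusted p = 0.0117) and the predicted miRNA m0002-3p (1.55, SE 0.32, adjusted p = 0.0117) were higher in Hezuo. Lower in Hezuo were miR-490, hosted by CHRM2 (-2.11, SE 0.49, adjusted p = 0.023), miR-29b (-0.85, SE 0.19, adjusted p = 0.0177), miR-532-5p (-0.67, SE 0.14, adjusted p = 0.0117) and miR-27a, a regulator of lipid metabolism (-0.57, SE 0.15, adjusted p = 0.0439). For every miRNA of this paragraph all 3 Hezuo livers lay beyond all 3 Bama livers, which the naming rule asked of all but miR-204-y. Of the 460 tested, 20.2% had non-overlapping groups, and chance gives 10%.

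In all, 20 entries passed, 11 higher and 9 lower in Hezuo, with 2 entries for miR-490 that hold the same counts (19 distinct). Liver-enriched miRNAs were higher as a list (16 of 25 positive, median 0.19, camera adjusted p = 0.00655; adjusted p = 0.8 with an estimated correlation; fry adjusted p = 0.182). Over all miRNAs 2 of them passed, miR-192-z (0.77, SE 0.16, adjusted p = 0.0117) and miR-194b-5p (2.97, SE 0.59, adjusted p = 0.0113), which was 2.10 without Hezuo cold 2 and is close in sequence to miR-194a-5p (-0.23, adjusted p = 0.48; chosen after its values were seen). Adjusted over the list alone 6 passed, with miR-215, miR-802, miR-194-x and miR-215-x added. The X-linked cluster of miR-424 and miR-503 was again lower in 10 of 10 members (median -0.50, adjusted p = 0.000127; adjusted p = 0.728 with an estimated correlation; fry adjusted p = 0.0318), with miR-450a (-0.54, SE 0.11, adjusted p = 0.011) and miR-542-3p (-0.53, SE 0.14, adjusted p = 0.0433) passing over all miRNAs and 5 adjusted over the list alone. The miR-29 family had 4 of 5 members negative (median -0.28, adjusted p = 0.207), with miR-29b and miR-29a-3p passing adjusted over the list alone. MiR-192-z, miR-194-x and miR-204-x are longer forms, and over 22 miRNAs the median log2 ratio of the longer to the shorter form was 0.27 higher in Hezuo over both temperatures. The liver-enriched list, which holds miR-192-z and miR-194-x, was not tested with forms summed. How far its call rests on longer forms is therefore unknown. MiR-122-5p (-0.12), miR-148a-3p (0.01), miR-192-x (0.31), miR-192 (-0.11), miR-143-3p (-0.26) and miR-122-3p (-0.11) had adjusted p of 0.312 to 0.961, and miR-210 was at -1.16 (adjusted p = 0.204).

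Of the distinct calls at the 2 temperatures, which share no libraries, 6 of those higher in Hezuo were the same (0.293 for independent lists of 12 and 11), among them miR-204 in its 3 forms and miR-192-z, and 2 of those lower (0.0889 for lists of 5 and 8), miR-184 and miR-9843-3p. MiR-9843-3p, chosen after its values were seen, was lost at normal temperature without Bama normal 3 (adjusted p = 0.0511) or Hezuo normal 3 (0.0608) and under cold without Bama cold 1 (0.0544). All 17 calls at normal temperature had the same sign under cold, and all 19 calls under cold had the same sign at normal temperature.

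Sums over shared first 16 nt gave 13 calls. In them miR-192 was at 0.28 (adjusted p = 0.328), miR-27a with its relatives at -0.24 (0.251) and miR-204 at 3.07, and miR-490 (0.0573), miR-29b (0.0534), miR-450a (0.16) and miR-542-3p (0.157) did not pass. Up and down calls of 11 and 9 became 13 and 5 with library totals and 14 and 7 with upper quartile scaling. With the pig number as a block, miR-27a (adjusted p = 0.0867) and miR-542-3p (0.0842) did not pass. Of 14 alternatives other than leaving out 1 library, these passed in 2 (DESeq2 and limma-voom), being lost under each other scaling and filter among others. Library totals also ended miR-532-5p and miR-450a, limma-voom ended miR-194b-5p, and the fit of the cold libraries alone ended miR-29b and miR-450a. The count was 7 without Bama cold 1 and 12 without Bama cold 3 or Hezuo cold 1. MiR-204, miR-204-x, miR-204-y, miR-184 and miR-340 passed in all 6 fits, with miR-204-x at 4.58 without Bama cold 2. MiR-450a was lost without Bama cold 1 (adjusted p = 0.0661), miR-6715-z and miR-194b-5p without Bama cold 1 or 3 (highest adjusted p 0.0776 and 0.0544), m0002-3p without Bama cold 1 or 2 (0.0776). MiR-532-5p was lost without Bama cold 1 or Hezuo cold 3 (0.0544), miR-29b without Bama cold 1 or 3 or Hezuo cold 1 (0.0935), miR-490 without Bama cold 2 or 3 or Hezuo cold 1 or 3 (0.11). MiR-192-z and miR-27a were lost without any but Hezuo cold 2 (0.0923 and 0.221) and miR-542-3p in all 6 (0.169). The liver-enriched list was lost without Bama cold 1 (0.116) or Hezuo cold 2 (0.054).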

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

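Of the tests in this part, those of the technical explanations for miR-192, miR-204 and the share of hepatocytes, and those of pairs of length forms, were chosen only after the result was seen. The miR-30 family stood out because its response to cold differed between the breeds by the interaction test: the median difference was -0.29 log2 units and 13 of 13 members were negative (adjusted p = 0.0464; adjusted p = 0.611 with an estimated correlation). Of 100 splits of the libraries, 71 gave at least 1 list, and the highest gave 7, so chance cannot be excluded for this count.

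For cold over both breeds, 1 of 100 splits (the real one, drawn from 200) gave as many as 10 miRNAs. The highest other split gave 2, so chance is unlikely to give this number of miRNAs. Chance remains open for the number of lists, where 31 of 100 splits gave at least 3 and the highest other gave 8. The correlation of the breeds' responses, 0.315, was reached by 1 of 100 splits, the real one, with 0.295 as the highest other. Chance is therefore unlikely, but not excluded, for the filtered fit of all 12 libraries. The margin was small, and only 100 of 200 splits were run. The correlation was 0.0532 without a filter and 0.169 to 0.276 with 1 library left out, fits for which other splits were not run. For the interaction edgeR called 0 miRNAs (25 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom), with 4 as the highest of the other splits. A count of 0 is reached by every split (100 of 100), so the splits decide nothing there. The comparisons of 3 against 3 have 10 splits, too few for a share under 0.05. Cold in Hezuo gave 0 miRNAs by edgeR (43 at an unadjusted p below 0.05, 0 by DESeq2 and limma-voom) and 0 lists by camera (4 at an unadjusted p below 0.05), with highest other values of 0 and 3. Cold in Bama gave 5 miRNAs and 4 lists, with highest other values of 2 and 6. The breed comparison gave 17 miRNAs and 2 lists at normal temperature, with highest other values of 0 and 4, and 20 miRNAs and 2 lists under cold, with highest other values of 0 and 5. As many were reached in 1 and 3 splits for Bama, 1 and 5 for the breeds at normal temperature and 1 and 7 under cold; for Hezuo, counts of 0 are reached by all 10 splits and decide nothing.

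The 24-nt form of miR-192 was lower under cold, at -0.72 (adjusted p = 0.0035). The 23-nt form at -0.34 (adjusted p = 0.0999) and the 21-nt form at -0.07 (adjusted p = 0.694) did not pass. The change of the 24-nt against the 21-nt form, -0.63, had an adjusted p of 0.00127 in a moderated t test over the 23 pairs of forms (SE 0.13; adjusted p 1.16e-05 to 0.0145 with 1 library left out). The exact permutation p of 0.005 is the smallest possible and could not pass after adjustment over the pairs, so it decides nothing there. Of the other pairs miR-221-y against miR-221-3p also passed, at -0.45 (adjusted p = 0.0393), but was lost without any 1 of 8 libraries (all but Bama cold 1, Hezuo normal 2, Hezuo normal 3 and Hezuo cold 3; adjusted p 0.0614 to 0.217). A loss of long inserts in the cold libraries would lower the longer form of other miRNAs as well. Over 22 of them the median change against the shorter form was 0.0417 (SD 0.18, 95% interval of the median -0.13 to 0.12). That lies above a cut-off of -0.31, set as a fraction of the miR-192 change after the result was seen. The forms of these pairs were at least 2 nt apart, and those of miR-192 had 21 and 24 nt. If the tags lost by the 23-nt and 24-nt forms together were counted under the 21-nt form, that form would rise by 0.61. Its change was -0.0740, with an interval of -0.28 to 0.13. Most of that loss was in the 23-nt form (45288 to 35777 CPM, against 5699 to 3474 CPM for the 24-nt form), whose fall did not pass. The rise needed for the 24-nt form alone was not computed, so for it this explanation stays open. A change of 3' end trimming or tailing of miR-192 with temperature may be considered as a hypothesis, untested here, and forms outside the table stay open.

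MiR-204 was higher in Hezuo livers by 2.21 at normal temperature. A breed variant that only changed how tags of the mature strand are counted would leave the opposite strand equal, but miR-204-y was higher by 2.83 (interval 1.87 to 3.799). RNA from endocrine islets, if it held at least as much miR-375 as miR-204, would raise miR-375 by 2.44. MiR-375 differed by -0.0551 (interval -1.46 to 1.35, with 74.1 CPM in Bama and 71.3 CPM in Hezuo). RNA from tissue with less miR-375 than miR-204 was not tested and stays open. The scaling does not account for it, since the lowest value over the 3 other scalings was 2.08, within the interval of 1.66 to 2.75. A higher output of the miR-204 gene in Hezuo livers may be considered as a hypothesis, with a variant of the hairpin, the mature strand included, left open.

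The share of miR-122-5p was lower and that of miR-148a-3p higher under cold. A rise of miR-148a-3p alone would leave the share of miR-122-5p in the other counts equal, and it changed by -3.12 percentage points (exact permutation p = 0.035), although p stayed under 0.05 only without Bama normal 2 (0.025), Bama cold 3 (0.035) or Hezuo cold 2 (0.025) and was up to 0.1 without any 1 of the other 9 libraries. Fewer hepatocytes would raise the markers of every other cell type alike. Over 40 markers of 6 cell types, each at 10 or more CPM, the median change was -0.03 (interval of the median -0.13 to 0.05, SD of single markers 0.28). The interval lies below a rise of 0.26, the size of the fall of miR-122-5p, so no common rise of that size was seen in TMM-scaled values. TMM scaling itself centres the values and can remove such a rise, so the median does not decide. The mean changes of the types ran from -0.18 for lymphoid to 0.31 for nervous and endocrine cells, and other arrangements of temperature within breed gave as wide a spread too often for this to decide (exact permutation p = 0.275). A smaller share of hepatocytes under cold therefore stays open. A response of hepatocytes to temperature may be considered beside it as a hypothesis, untested here.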

How the results depend on the processing

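The sums over shared first 16 nt, the collapse of identical entries and the omission of short entries ending in CCA were chosen after seeing the data, and all other alternatives before. Over the alternatives other than leaving out 1 library, the named miRNAs kept their direction and their side of the threshold in 1277 cases, no longer passed in 116, newly passed in 13 and changed sign in 24. With 1 library left out these numbers were 678, 128, 8 and 32. Lists that passed kept both in 25 cases and were lost in 23, and with 1 library left out in 64 and 32. The cause was not tested for any of the values below.

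Numbers of miRNAs that moved by over 1.5 times were, for cold in Bama (5), 1 with library totals, 3 with a mean of 10 counts, 21 with DESeq2, 0 with edgeR on the compared groups alone (67 at an unadjusted p below 0.05 in the fit of all libraries, 4 by limma-voom), 2 with the pig number as a block (miR-29a-3p, miR-181-y and miR-192-z lost), 3 with shared first 16 nt summed, and 20 at unadjusted p below 0.05 with a 2-fold change. That last threshold gave 8 for cold in Hezuo, 13 for the interaction, 6 over both breeds and 36 for the breeds at normal temperature. Over both breeds (10) the numbers were 6 without a filter, 26 with DESeq2 and 5 with 16 nt summed. For the breeds at normal temperature (17) they were 27 with upper quartile scaling, 37 with DESeq2, 10 with the compared groups alone, 11 with the block, 32 without the most abundant miRNA and 27 without the CCA entries. Under cold (20) 13 passed with 16 nt summed. The block gave 0 for cold in Hezuo, 8 over both breeds, 0 for the interaction by edgeR and 16 for the breeds under cold. With 1 library left out, the numbers lay at 0 to 5 for cold in Bama, 5 to 12 over both breeds, 4 to 24 for the breeds at normal temperature and 7 to 21 under cold.

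Numbers of lists were 0 by camera with an estimated correlation in every comparison where lists passed. Library totals gave 1 list for cold in Bama and 0 for the interaction, where the block and fry also gave 0. Fry gave 1 for the breeds at either temperature. With 1 library left out, the numbers were 0 to 1 for cold in Hezuo, 2 to 4 for cold in Bama, 0 to 1 for the interaction, 0 to 3 over both breeds and 1 to 3 for the breeds under cold. The correlation of the breeds' responses was 0.0532 without a filter, 0.469 at 10 or more CPM, 0.314 with the block, and 0.169 to 0.276 with 1 library left out.

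Signs changed in values that had not passed. For miR-192 the value was 0.12 for cold in Hezuo and 0.00317 over both breeds with library totals, 0.00465 for cold in Bama and -0.0540 for the interaction with upper quartile scaling, and 0.27 and 0.28 for the breeds at normal temperature and under cold with 16 nt summed. For miR-143-3p it was 0.0679 for cold in Bama with upper quartile scaling. For miR-148a-3p the interaction was 0.000657 with library totals. For miR-192-x the interaction was 0.15 with library totals, 0.0397 without the most abundant miRNA, 0.00904 with identical entries collapsed, 0.0138 with 16 nt summed and 0.00362 without CCA entries. For miR-122-3p the interaction was 0.00965 with DESeq2 size factors, 0.15 with library totals, 0.0215 without a filter, 0.000561 with DESeq2, 0.0145 without predicted miRNAs, 0.0648 without the most abundant miRNA, 0.0424 with identical entries collapsed, 0.0420 with 16 nt summed and 0.0301 without CCA entries. For the breeds at normal temperature miR-122-3p was 0.0513 with upper quartile scaling and miR-210 was -0.0114 with 16 nt summed.

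With 1 library left out, the values whose sign changed lay between -0.127 and 0.0880 for miR-192 in Hezuo cold, between -0.165 and 0.195 for miR-143-3p and -0.312 and 0.188 for miR-122-3p in Bama cold. Over both breeds they lay between -0.126 and 0.00683 for miR-192, -0.00639 and 0.178 for miR-143-3p, and -0.234 and 0.0246 for miR-122-3p. In the interaction they lay between -0.193 and 0.0872 for miR-192-x, -0.0508 and 0.211 for miR-192, -0.0340 and 0.319 for miR-143-3p, and -0.327 and 0.156 for miR-122-3p. Between the breeds they lay between -0.0253 and 0.265 for miR-122-5p and -0.254 and 0.212 for miR-122-3p at normal temperature, and between -0.0901 and 0.0857 for miR-148a-3p and -0.225 and 0.0371 for miR-192 under cold. Library totals moved the median of all miRNAs by 0.17 for cold in Hezuo. Depth limits rare entries: 3 counts over the Bama normal group correspond to 0.134 CPM. The alternatives for normalized values alone were not run, since counts were deposited.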

Other observations

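All tests in this part were chosen after the result was seen. Hezuo libraries held more of the longer forms of miRNAs, relative to the shorter, than Bama libraries. Batch is not given, so a difference in size selection or preparation between the breeds' libraries cannot be told apart from one between the livers. Over 22 miRNAs listed at 2 lengths at least 2 nt apart, the median log2 ratio of the longer to the shorter form was higher in Hezuo by 0.27 (exact permutation within temperature p = 0.005, the smallest possible), with 19 of 22 pairs in that direction. Between temperatures the difference was 0.06 (exact permutation within breed p = 0.38).

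The predicted miRNA m0017-3p had 0 counts in all Bama libraries, against 75 counts in Hezuo normal and 74 in Hezuo cold livers. With a floor of 3 counts over the Bama group it was at least 20.1-fold higher in Hezuo at normal temperature and at least 26.4-fold higher under cold, counting error only. Hezuo cold 2 held 51 of the 74 counts, and without it the bound under cold was 12.6-fold. With the same floor it was 15.8-fold without Bama cold 1, and the bound at normal temperature was 13.3-fold without Bama normal 2. MiR-6715-z and the predicted miRNA m0002-3p, both higher in Hezuo under cold, were complementary at 16 of 21 bases. The summed level of the 13 measured members of the imprinted DLK1-DIO3 cluster was 342 ± 167 CPM (SD, n = 3) in Bama normal, 289 ± 181 in Bama cold, 626 ± 483 in Hezuo normal and 342 ± 77.5 in Hezuo cold livers. Hezuo normal 2 alone had 1157 CPM, and without it the Hezuo normal mean was 360 CPM; without Bama cold 2 the Bama cold mean was 187 CPM.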
